A study of Mus musculus with 6 samples.

How the data were processed

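The series holds 6 samples of RNA pulled down with tagged ribosomes from mouse cortex, 3 from the S100a10 line (ES691) and 3 from the Glt25d2 line (DU9), on a background crossed from FVB to C57BL/6 per the labels. RNA was labelled with biotin after a 2-cycle amplification from 15 ng and hybridised to Affymetrix mouse whole-genome arrays of probe sets, per the labels. The authors' deposited values are intensities on a linear scale after GCRMA, per the submitters' processing notes, which corrects the background by the base composition of probes, normalizes quantiles and summarises each probe set by median polish. Its software version is not given in the sources used here. The series text says that replicates were averaged, but the table holds 6 separate columns, which were used. It also proposes a limit of 50 on the values and a list of probe sets from a table of the paper; that list is not used here. The table's quantiles differ between the groups and hardly within them: the mean absolute difference between sorted log2 values of 2 arrays was 0.0174 to 0.0811 within a group and 0.447 to 0.508 between groups. At least 2 arrays of a group held the same value in 46.8% of probe sets for Glt25d2 and in 0.98% for S100a10. Differences between the groups may therefore carry a part of unknown size set by the scaling.

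Of 45101 probe sets, 64 controls were left out of all tests. In the platform annotation 34945 of the others name 1 gene, 932 several and 9160 none, and genes were named only from probe sets with 1 symbol. Entrez identifiers of 34741 were found in the RefSeq gene table for GRCm38.p6, and 0 symbols changed. That table's coordinates are not printed, since the files name no genome build, and it was used for names and neighbouring genes only. Intensities were taken to log2 without a pseudocount, and probe sets with a mean of at least 50 in at least 1 group were kept. For a gene, the kept probe set with the highest mean log2 over the 6 arrays was used. Where every array of a group lay under 50, the fold is a bound computed against 50. It is a bound for the deposited scaling only, and toward S100a10 a rescaled fit can fall below it. The number of arrays limits the precision of every value.

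S100a10 minus Glt25d2 was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjustment, threshold 0.05), without a block, and a fold of at least 2 was counted separately. Gene lists, 30 in all, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. A list needed 3 measured members, so 28 were tested; sex-linked genes had 2 measured members and blood genes 0. The comparison, lists, filter, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the driver genes, the 12 genes with the largest differences in each direction among those past the threshold with arrays that do not overlap, up to 4 genes of each list with the largest differences and any other member a count rests on, and the measured serotonin receptors. Values under every alternative were computed for the drivers, the 12 genes of each direction, those up to 4 genes and the serotonin receptors. All other list members were compared in 4 fits. Genes named outside it were chosen after their values were seen. The sample titles add a letter b to the replicate numbers of S100a10 and none to those of Glt25d2. The replicate numbers are not used as pairs.

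On simulated data for this comparison, with means and spreads of the 11821 genes and 50 genes changed at each fold, 6 of 50 genes changed 1.5-fold were called, 23 changed 2-fold, 35 changed 4-fold and 45 changed 8-fold, all with the right sign, and 5 unchanged genes were called. With no change, 0 lists were called, and a shifted list was recovered. The simulation drew each gene independently and held no identical values within a group. It changed 200 of the 11821 genes, whereas 5827 genes passed in the data. The adjustment is stricter where fewer genes change, so the shares called in the simulation do not carry over to the data. It cannot show how the list test behaves where genes vary together.

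Alternatives were no filter, both means or the mean of all arrays at 50 or more, a pseudocount of 16, values under 50 set to 50, quantile normalization, median centring, the replicate number as a block, a trended prior, array weights, the mean of a gene's probe sets, an ordinary 2-sample test with equal variances for probe sets, and each array left out. Quantile normalization together with leaving out Glt25d2 replicate 3 was added after the data were seen. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.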

Results

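RNA bound to tagged ribosomes was measured in 2 groups of cortical cells from transgenic mice. In translating ribosome affinity purification (TRAP), a bacterial artificial chromosome (BAC) with the control regions of a driver gene places a tagged ribosomal protein in the cells that use that gene, and the ribosomes of these cells are pulled from a tissue lysate with their messenger RNA. The drivers were S100a10, which encodes a small protein that binds annexin A2, and Glt25d2, a collagen galactosyltransferase gene now named Colgalt2. Each group held 3 biological replicates by the sample titles, each on 1 array, and the study compared the 2 lines as populations of cortical pyramidal cells. The series text also says that the S100a10 transgene marks some cells other than neurons. The median intensity of the probe sets was 21.3, 21.1 and 20.4 in the Glt25d2 arrays and 35.5, 35.6 and 35.8 in the S100a10 arrays, and the number of arrays limits the precision of every value. All differences are log2 values of S100a10 minus Glt25d2 with limma's adjusted p (Benjamini-Hochberg).

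Each driver gene was higher in its own line. S100a10 had a mean intensity of 15486 ± 2417 in S100a10 arrays against 3237 ± 179 in Glt25d2 arrays (SD, n = 3 each), a log2 difference of 2.25 (SE 0.14, limma adjusted p = 1.07e-04). Colgalt2 had 1077 ± 263 in Glt25d2 arrays against 11.6 ± 0.198 in S100a10 arrays (SD, n = 3 each), a difference of -6.51 (SE 0.19, limma adjusted p = 9.42e-06), and since every S100a10 array lay under 50 its level was at least 21.1-fold higher in Glt25d2 cells. A BAC can carry its driver gene or part of it, so these values check the labels and are no independent measure of the cell type.

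By the fixed rule, the 12 genes with the largest fitted differences in each direction are named here. Where every array of 1 group lay under 50, the fitted difference rests on background-level values, and only a bound against 50 is given. The bounds hold for the deposited scaling, and toward S100a10 a rescaled difference can lie below them. Foxd1, a forkhead transcription factor, had a mean of 18.2 in Glt25d2 and 8273 in S100a10 arrays and was at least 165-fold higher in S100a10 cells. Ogn, which encodes the matrix protein osteoglycin, was at least 115-fold higher, Mpzl2 at least 109-fold, Crabp2 at least 87.9-fold and Foxc2, another forkhead factor, at least 46.0-fold. The bounds were 38.5-fold for Islr, 31.7-fold for Dapl1, 21.3-fold for Bnc2 and 21.2-fold for Emp3. Nupr1 differed by 7.47 (SE 0.13) and Mgp, the matrix Gla protein, by 7.26 (SE 0.58), or 6.58 without Glt25d2 replicate 3. Slc6a20a differed by 7.27 (SE 0.86), a value that is uncertain because 2 of 3 Glt25d2 arrays and their mean of 34.4 lay under 50; it was 6.34 without Glt25d2 replicate 3 and 8.09 without Glt25d2 replicate 2. Toward Glt25d2 cells, besides Colgalt2, Sox17 differed by -3.96 (SE 0.28), Tsen15 by -2.99 (SE 0.14) and Grp, gastrin-releasing peptide, by -2.86 (SE 0.67). Grp was -3.50 without Glt25d2 replicate 3 and did not pass when Glt25d2 replicate 2, S100a10 replicate 1 or S100a10 replicate 3 was left out. The others had bounds only: Ddc, aromatic amino acid decarboxylase, was at least 11.2-fold higher in Glt25d2 cells, Ctla2a 6.06-fold (9.86-fold without Glt25d2 replicate 3), Ctla2b 5.32-fold, Nostrin 4.09-fold, Erg 3.53-fold, Cyyr1 3.13-fold, She 2.41-fold and Tdo2, tryptophan dioxygenase, 2.37-fold. Sox17 and Erg are transcription factors known from blood vessel endothelium. All of these genes had adjusted p values of 0.0155 or lower. Passing the threshold and arrays that do not overlap were conditions of the rule that chose them. Each kept its direction under quantile normalization, under median centring and without Glt25d2 replicate 3. The rescaled fits do not test this. They move most genes toward Glt25d2, and the move of the median gene, from 0.56 to -0.04 after quantile normalization, is small against the differences toward S100a10.

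**Figure D1:**
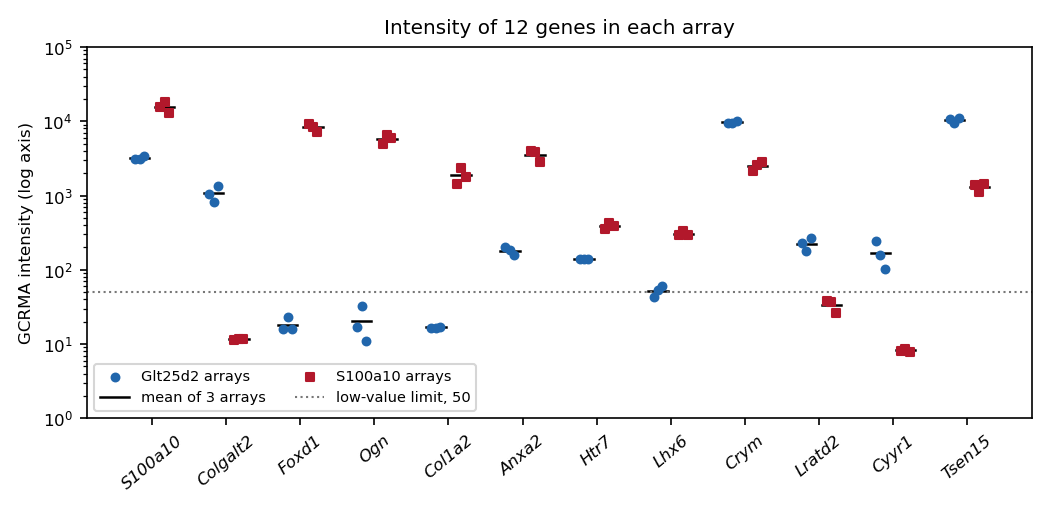
GCRMA intensity of 12 genes on a log axis in each of the 6 arrays, with circles for the 3 Glt25d2 arrays, squares for the 3 S100a10 arrays, black bars for the means and a dotted line at the low-value limit of 50. S100a10 (means 3237 and 15486) and Colgalt2 (1077 and 11.6) are each higher in their own line. The arrays of the 2 groups do not overlap for any of the 12 genes, which was a condition for choosing Foxd1, Ogn, Cyyr1 and Tsen15.

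Of 11821 genes tested, 5285 were higher in S100a10 cells and 542 in Glt25d2 cells, and 2849 and 123 of these differed at least 2-fold. Counts in the gene lists below are to be read against these shares of all genes. A smaller share than that of all genes rose in several lists. Among these were intratelencephalic neurons, interneurons, astrocytes, glutamate receptors, potassium channels, peptides and the respiratory chain. At the level of probe sets, 9405 of 21291 were higher in S100a10 cells and 934 in Glt25d2 cells, so 91.0% of the calls pointed to S100a10. This share fell to 41.8% after quantile normalization of the 6 arrays, with 3289 and 4585 probe sets, and to 40.2% after centring each array on its median, with 3456 and 5131. The median gene differed by 0.56 as deposited, by -0.04 after quantile normalization and by -0.14 after centring, so list medians below are given relative to the median of all genes. Of the 5285 genes higher in S100a10 cells, 2079 were also called in that direction after quantile normalization and 83 in the other. Genes higher in Glt25d2 cells are not tested by this step, since it moves most genes in their direction. Of the genes tested, 7546 had values that did not overlap between the groups. Chance gives 10% only for arrays without a shift between the groups. A shift of most genes by itself raises this count, which was not computed after rescaling, so it does not measure a difference between the cells. At least 2 of the 3 Glt25d2 arrays held identical values for 2609 of the tested genes, whose spread in that group is therefore understated. Of those genes 74.9% passed the threshold, against 42.0% of the others. Without Glt25d2 replicate 3, 6606 genes were higher in S100a10 cells and 748 in Glt25d2 cells.

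Genes of subcerebral projection neurons, the layer 5 cells whose axons leave the cortex downward, were lower in S100a10 than in Glt25d2 cells. Of 13 measured members 6 fell, 1 rose and 6 did not pass. The number lower was 9 after quantile normalization, 10 after centring and 9 without Glt25d2 replicate 3, or 11 in that fit after quantile normalization, with 1 higher each time. The list median lay at -1.73 relative to all genes, or at -1.06 with values under 50 set to 50, and camera gave an adjusted p of 7.8e-08, between 1.28e-10 and 0.0028 under the 18 alternatives of the fit, and an adjusted p = 0.203 with an estimated correlation. The transcription factors Fezf2 and Bcl11b, which specify these neurons, differed by -1.24 (SE 0.13) and -1.66 (SE 0.21). Crym, a thyroid hormone-binding protein, fell from a mean of 9719 ± 378 to 2503 ± 331 (SD, n = 3 each), a difference of -1.97, and Lratd2 and Diaph3 were at least 4.44-fold and 1.41-fold lower. Opn3, an opsin, rose by 2.01. Of 13 genes of intratelencephalic neurons, whose axons stay within the forebrain, 5 rose and none fell. This share of rises was below that of all genes, 5285 of 11821. The 5 included Plxnd1, a semaphorin receptor, at 1.72 and Lmo4 at 1.11. After centring 2 of the 13 were higher and 2 lower, without Glt25d2 replicate 3, 8 and 2, and after quantile normalization as well 6 and 3. The list did not pass (camera adjusted p = 0.988). Of 8 upper-layer genes 4 rose and 1 fell: Rspo1, a Wnt agonist, at least 5.56-fold, Lhx2 by 2.56, Rorb, a nuclear receptor of layer 4, by 2.34 and Cux1 by 1.04, against Calb1 at -0.58 (camera adjusted p = 0.948). Without Glt25d2 replicate 3, 6 were higher and 1 lower. Cux1 did not pass after quantile normalization or centring, and Lmo4 not after centring. Rspo1 differed by a log2 value of 2.23 after quantile normalization, which as a fold lies below its bound.

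Genes of corticothalamic and layer 6b neurons were split. Of 11 measured, Ccn2 at 2.65 and Rprm at 0.72 were higher in S100a10 cells, Nr4a2 at -1.01 and Cplx3 at -0.87 were lower, and 7 did not pass. The counts were 5 higher and 3 lower without Glt25d2 replicate 3, and 1 and 7 after quantile normalization as well; Ccn2 was then 1.95 and 1.56, and Rprm did not pass after quantile normalization or centring with all arrays. The list was called lower (camera adjusted p = 0.0343; adjusted p = 0.891 with an estimated correlation), which did not hold after quantile normalization (0.341, within 0.00429 to 0.383 over the 18 alternatives, of which 11 passed), nor without Glt25d2 replicate 2 (0.126). Ccn2 did not pass without S100a10 replicate 1 or 2. Among 11 interneuron genes the neuropeptides Npy and Sst rose by 3.46 and 2.88, and the transcription factors Lhx6 and Dlx1 by 2.57 and 1.38, while Pvalb, the calcium buffer of fast-spiking cells, fell by 2.43; 6 did not pass and neither did the list (camera adjusted p = 0.565). Npy and Sst were low in Glt25d2 replicate 3, at 77.0 and 76.6, and without that array they differed by 2.59 and 1.97; Sst did not pass after centring or with any S100a10 array left out, and Npy not without S100a10 replicate 2 or 3. The counts were 5 higher and 3 lower without Glt25d2 replicate 3, and 4 and 4 after quantile normalization as well. Of 13 pan-neuronal and excitatory genes 4 rose, among them the glutamate transporter Slc17a7 by 2.12 and the synapsin Syn1 by 1.64, and 2 fell, Gap43 by 0.98 and Map2 by 0.74, with 2 higher and 6 lower after centring (camera adjusted p = 0.421). Slc17a7 was 1.60 without Glt25d2 replicate 3.

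Markers of other cell types differed as well. Whether their messengers came from tagged cells or from other cells of the lysate was not tested. Of 11 genes of mural cells and fibroblasts 10 rose, with a list median of 4.80 relative to all genes, or of 3.70 with values under 50 set to 50. They included the collagen Col1a2, at least 36.6-fold higher, the myosin light chain Myl9, at least 32.2-fold, and the growth factor receptor Pdgfrb, at least 17.2-fold, whereas Rgs5, a signalling regulator of pericytes, fell by 0.88. Camera called the list higher (adjusted p = 0.00673; adjusted p = 0.891 with an estimated correlation), and the call ended without a filter and with both group means at 50 or more (0.475, within 2.17e-06 to 0.475 over the alternatives), a filter that removes genes low in 1 group. All 4 ependymal and choroid plexus genes rose, led by Rarres2, at least 11.5-fold higher, and 2 of them passed after quantile normalization or centring (list adjusted p = 0.191). Clic6 at 0.56 took a negative sign in both fits, and Ttr, which rests on 1 S100a10 array at 261 with every other array under 50, did not pass in either, nor with Glt25d2 replicate 1 or 2 or S100a10 replicate 2 left out. Of 12 astrocyte genes 4 rose and 2 fell. Gjb6, a connexin, rose by 6.26 and Aldh1l1, a folate enzyme, by 2.23, while Gfap, an intermediate filament, was at least 1.98-fold lower and Aldoc fell by 1.07 (list adjusted p = 0.828). Leaving out Glt25d2 replicate 3 gave 8 higher and 3 lower, or 3 and 3 after quantile normalization as well, and Gjb6 at 5.43 without quantile normalization; Gjb6 was 6.96 without Glt25d2 replicate 2. Of 6 microglial genes only Tmem119 passed, at least 3.99-fold higher, with Csf1r at -0.021 (list adjusted p = 0.948), and of 5 genes of oligodendrocyte precursors only Pdgfra, at 2.50 (list adjusted p = 0.663). Pdgfra did not pass after quantile normalization or centring and was 1.72 without Glt25d2 replicate 3, the only array whose removal, besides that of Glt25d2 replicate 2, left it past the threshold; it was 3.19 without the latter.

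Oligodendrocyte genes were lower in S100a10 cells as a list (camera adjusted p = 0.00165; adjusted p = 0.891 with an estimated correlation), with 2 of 11 falling, Ermn by 1.52 and the myelin protein gene Mbp by 0.95, 1 rising, the transcription factor Olig2, at least 1.78-fold, and 8 not passing. Olig2 did not pass after quantile normalization or centring, and Mbp not without S100a10 replicate 1 or 3. The log2 difference of Olig2 was 0.44 after quantile normalization, which as a fold lies below its bound. In the fit without Glt25d2 replicate 3, 6 were lower and 2 higher, and 9 and 1 after quantile normalization as well. The list call was lost after quantile normalization (0.113, within 4.13e-06 to 0.145 over the alternatives). Of 6 endothelial genes Esam fell by 0.97 and Eng rose by 0.79, the latter turning to -0.048 after quantile normalization (list adjusted p = 0.055). Without Glt25d2 replicate 3, 4 of them were lower in S100a10 cells and 1 was higher, with an adjusted p of 1.88e-04 for the list, within 1.88e-04 to 0.384 over the alternatives, of which 5 passed. The list had an adjusted p = 0.911 with an estimated correlation and all arrays, and without that array no list passed with an estimated correlation.

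**Figure D2:**
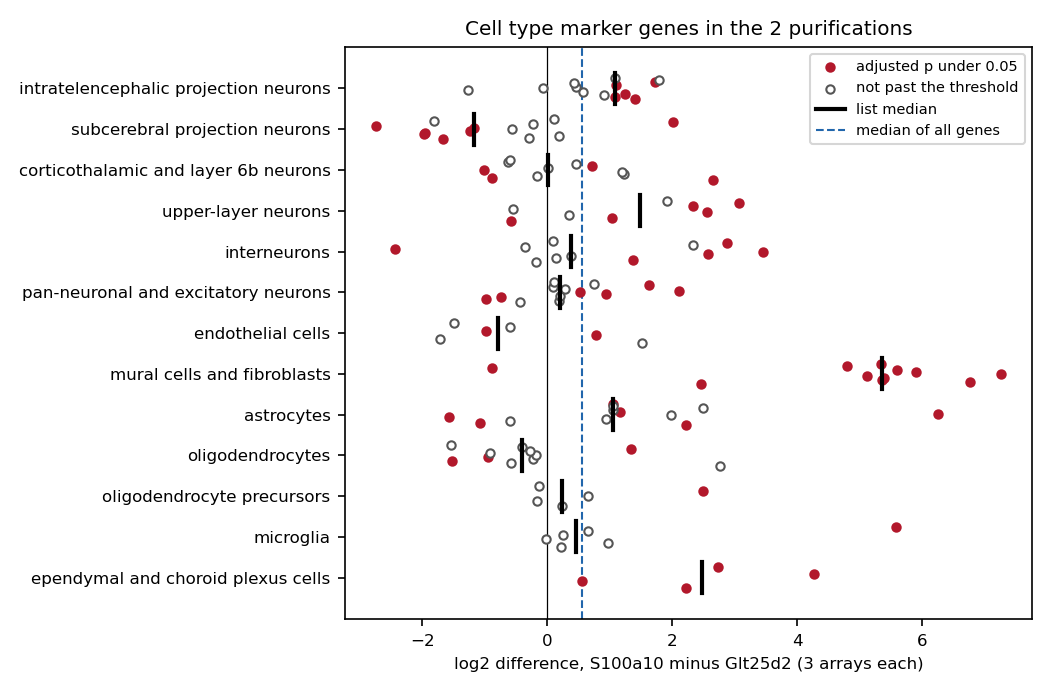
Log2 difference of each measured gene (points) in 13 lists of cell type markers, S100a10 minus Glt25d2 with 3 arrays each; filled points passed an adjusted p of 0.05, open points did not, black bars are list medians, values under 50 enter as measured, and the dashed line is the median of all genes at 0.56. The list of mural cells and fibroblasts has the highest median of the 13, with Rgs5 at -0.88, and 6 of 13 genes of subcerebral projection neurons passed to the left of 0. Of the genes that passed, Eng and Clic6 take a negative sign after quantile normalization, and Clic6 and Rbfox3 after centring.

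The family of the driver S100a10 was higher in the S100a10 arrays. Genes of mural cells and fibroblasts were higher there too, with a list median of 4.80 relative to all genes. Which cells carry the messengers of the family and of the partners below was not tested. Of 14 measured S100 and annexin genes 12 rose, the driver among them, or 13 when adjusted over the list alone, and none fell; the list median was 1.72 relative to all genes, or 1.59 with values under 50 set to 50 (camera adjusted p = 0.00471, within 6.36e-06 to 0.0204 over the alternatives; adjusted p = 0.891 with an estimated correlation). Anxa1 rose by 4.99 (SE 0.25), Anxa2, which binds the S100a10 protein, by 4.28 (SE 0.18), S100a6 by 3.53, and S100a4 was at least 3.31-fold higher. Of 7 partners listed for the S100a10 protein 5 rose, with the scaffold protein gene Ahnak at least 10.5-fold higher; Kcnk3 at 0.99 and Htr1b at 0.71 took negative signs, -0.073 and -0.084, after quantile normalization without Glt25d2 replicate 3, as did Hltf at 0.39 after quantile normalization (list adjusted p = 0.228). After quantile normalization 2 partners were higher, and the list median fell from 0.87 relative to all genes to 0.091 without Glt25d2 replicate 3. Kcnk3 did not pass without S100a10 replicate 2 or 3, and Htr1b not without S100a10 replicate 1 or 3. Of 6 serotonin receptors measured, Htr7 rose by 1.46 (SE 0.10), from 140 in every Glt25d2 array to 387 ± 33.7 (SD, n = 3) in S100a10 arrays. The identical Glt25d2 values understate its spread. Htr7 differed by 0.70 after quantile normalization and by 0.76 after centring. Htr1b rose by 0.71 (SE 0.18), or 0.017 after quantile normalization. Htr2c at 1.05 (SE 0.84), Htr5a at 1.04 (SE 0.36), Htr1f at 0.61 (SE 0.51) and Htr1a at 0.28 (SE 0.18) did not pass, and each took a negative sign in at least 1 of the rescaled fits. Htr5a passed without Glt25d2 replicate 1 or 3, and Htr2c was 0.071 without Glt25d2 replicate 3. The Htr4 probe sets lay under 50 in every array. The receptor list did not pass (camera adjusted p = 0.789).

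Many receptors, channels and secreted peptides, most of whose messengers are translated at the endoplasmic reticulum, were low in Glt25d2 replicate 3. In that array 993 of the 11821 genes lay over 4-fold below the mean of the other 2 Glt25d2 arrays and 2 lay over 4-fold above. Members of the receptor, channel and peptide lists deviated there by a median of -1.65 against -0.024 for lists of cytosolic proteins. Some members, such as the nuclear receptors Esr1 and Nr3c1 and the cytosolic subunits Kcnip2 and Kcnab1, were not low there. Potassium channels included 15 of 41 that rose and 3 that fell, with Kcnk2, a mechanosensitive 2-pore channel, at 3.42 (SE 0.14) and Kcnip2, a channel-binding protein, at 2.16; after quantile normalization 7 were higher and 7 lower, and without Glt25d2 replicate 3 the counts were 19 and 7, or 10 and 13 after quantile normalization as well. Kcnab3, 1 of the 15 at 0.30, was called lower after quantile normalization (-0.37), after centring (-0.40) and after quantile normalization without that array (-0.33), and it did not pass without that array as deposited. Of 25 sodium, calcium and HCN channel genes 7 rose, or 10 with 2 falling without that array, and 5 with 9 falling after quantile normalization as well. Of 19 glutamate receptor genes 4 rose, led by Grik5 at 3.18, or 2.44 without that array. After quantile normalization 1 was higher and 1 lower, without that array 7 and 5, and in both together 6 and 10. Of 10 GABA receptor genes none passed, against 2 lower without that array and 6 lower after quantile normalization as well. Of 18 peptide, cannabinoid and steroid receptors 3 rose, Npy1r at least 1.73-fold, Tacr3 by 2.68 and Crhr1 by 2.49, and the estrogen receptor Esr1 fell by 0.98; without that array 5 were higher and 5 lower, or 3 and 10 after quantile normalization as well. Of 8 catecholamine, acetylcholine and histamine receptors 3 rose, Chrnb2, Hrh3 and Hrh1, with 1 higher and 1 lower after quantile normalization, 5 and 1 without that array, and 1 and 3 in both together. Chrnb2 and Hrh1 did not pass without S100a10 replicate 2 or 3, nor Chrnb2 without S100a10 replicate 1 or Glt25d2 replicate 2. Of 20 neuropeptides and trophic factors 7 rose, with Igf2 at 6.79 (SE 0.14), Igf1 at least 4.45-fold higher and Tac2 at least 2.32-fold, and Grp fell by 2.86, or 3.50 without Glt25d2 replicate 3. Without Glt25d2 replicate 3, 7 were higher and 6 lower, and 5 and 8 after quantile normalization as well. Of 40 axon guidance genes 8 rose, among them the semaphorin Sema3d, at least 3.67-fold, and 1 fell, Sema6a. Without Glt25d2 replicate 3, 14 were higher and 8 lower, and 6 and 19 after quantile normalization as well.

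None of these 8 lists passed as deposited with arrays of equal weight, at camera adjusted p values of 0.565 for potassium channels, 0.982 for the other channels, 0.517 for glutamate and 0.191 for GABA receptors. They were 0.278 for peptide receptors, 0.948 for amine receptors, 0.751 for peptides and 0.388 for axon guidance. With array weights 5 of the 8 were called lower, those of glutamate, GABA and peptide receptors, peptides and axon guidance, and the same 5 without Glt25d2 replicate 3, each with an adjusted p = 0.988 with an estimated correlation and all arrays. Without Glt25d2 replicate 3, 11 of the 28 lists were called lower in S100a10 cells. In that fit the GABA receptors had a median of -0.63 relative to all genes, the glutamate receptors of -0.41 and the peptides of -0.50, and none of the 28 lists passed with an estimated correlation (lowest adjusted p with all arrays 0.203).

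**Figure D3:**
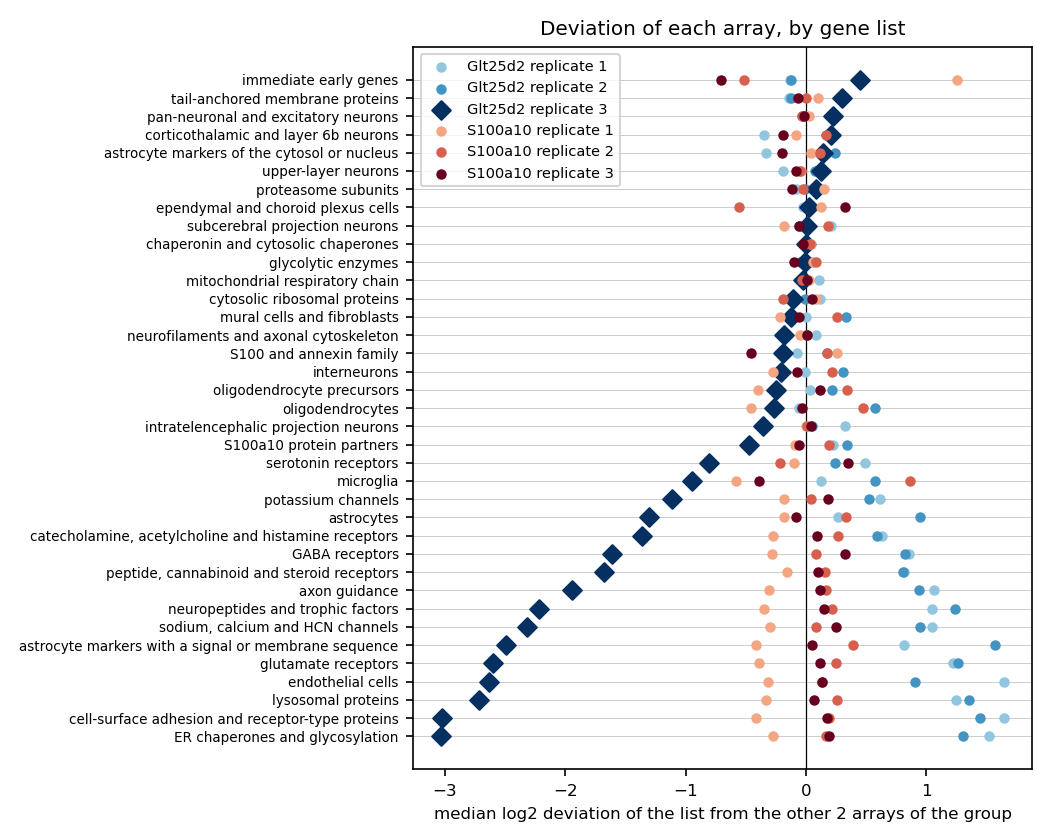
Median log2 deviation of each gene list in each array from the mean of the other 2 arrays of its group; diamonds are Glt25d2 replicate 3 and circles the other 5 arrays. Adhesion, chaperone and lysosomal lists lie near -3 in Glt25d2 replicate 3 (-3.02, -3.03 and -2.72), whereas the respiratory chain lies at -0.024 and tail-anchored membrane proteins at 0.30.

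Of 43 respiratory chain genes 12 rose, or 11 adjusted over the list alone, and 3 fell, with medians of 0.17 as deposited and -0.056 after quantile normalization (camera adjusted p = 0.121); 2 were higher and 8 lower after quantile normalization, and 0 and 30 after centring, where Ndufb5, at 0.34 and past the threshold as deposited, was called lower at -0.37. The list was called lower after centring (adjusted p = 4.88e-06) and without Glt25d2 replicate 3 (0.0132), within 4.88e-06 to 0.765 over the alternatives, with an adjusted p = 0.988 with an estimated correlation and all arrays. Of 27 cytosolic ribosomal protein genes 13 rose, or 16 adjusted over the list alone, with a median of 0.35, or -0.21 relative to all genes, which centring does not change. After centring 0 genes were higher and 9 lower, and the list was called lower (adjusted p = 0.0419, within 0.0419 to 0.91 over the alternatives, and 0.687 as deposited; adjusted p = 0.988 with an estimated correlation). Of 16 immediate early genes Nr4a3 fell by 1.43, and Egr1 at 0.45 and Jun at 0.39 passed but took negative signs after centring, and each lost its call without Glt25d2 replicate 1 or 2, Jun also without S100a10 replicate 1 or 3, and Nr4a3 without S100a10 replicate 2 (list adjusted p = 0.212, and 0.0135 to 0.957 over the alternatives, passing as lower without S100a10 replicate 1; adjusted p = 0.988 with an estimated correlation). Of 13 neurofilament and axonal genes 4 rose, or 3 adjusted over the list alone, with Sncg, a synuclein, at least 5.28-fold higher, and 1 fell, the neurofilament gene Nefm by 0.73 (list adjusted p = 0.121, and 0.0259 to 0.443 over the alternatives, the lowest without Glt25d2 replicate 3; adjusted p = 0.891 with an estimated correlation). After quantile normalization 1 was higher and 6 lower, and without Glt25d2 replicate 3, 4 and 3. Sncg differed by a log2 value of 1.56 after quantile normalization, which as a fold lies below its bound. Adjusted over the list alone, upper-layer genes had 4 higher and 2 lower and oligodendrocyte precursors 0 higher, and 22 of the 28 lists kept their counts. For 9 lists the camera direction opposed the sign of the median relative to all genes: intratelencephalic neurons, astrocytes, amine receptors, glutamate receptors, both channel lists, axon guidance and peptides (median above, test below) and ribosomal proteins (median below, test above). The mean lay above and the median below that of all genes for interneurons (0.18 and -0.17) and microglia (0.52 and -0.11).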

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

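The tests in this part were chosen after the results were seen, the counts under other splits of the arrays included. The control probe sets, which no comparison used, carried a signal that differed between the groups. The 24 probe sets for Bacillus poly-A spikes, RNAs added to a sample before amplification, had a median log2 difference of 2.05, with all 24 higher in every S100a10 array than in any Glt25d2 array. Their median intensities were 22.1, 21.9 and 20.2 in the Glt25d2 arrays, under 50, and 118, 98.2 and 87.3 in the S100a10 arrays. The size of the difference therefore rests on background-level values in Glt25d2 and is uncertain. The probe sets for hybridization controls, added after amplification, differed by a median of -0.006, and the trp probe sets, which are not spiked, by 0.30. Sample preparation may therefore have differed between the groups, which was not tested. Such a difference cannot be told apart from the line in any comparison here.

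Glt25d2 replicate 3 lacked messengers of proteins made at the endoplasmic reticulum. Hspa5, a chaperone of that compartment chosen after its values were seen, had 11008 and 13441 in replicates 1 and 2 and 320 in replicate 3, while Aldoa, a cytosolic enzyme, had 33521, 32519 and 29967. RNA degradation throughout the sample is argued against by the Actb ratio of 5' to 3' probe sets, 0.261 in replicate 3 and 0.199 and 0.217 in the others. Actb encodes a cytosolic protein, so its ratio does not report on the messengers that were low there. Another mix of cells is argued against by astrocyte markers, whose membrane members had a median deviation of -2.63 relative to cytosolic and nuclear ones, as 1 cell type should not. What stays open, as a hypothesis, is that membrane-bound ribosomes may have been lost from that sample: 147 genes of receptor, channel and peptide lists, a few of them nuclear or cytosolic, deviated by -1.63 relative to 86 cytosolic genes, in lists fixed before the data were examined but sorted into these classes afterwards.

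Most probe sets were higher in the S100a10 arrays, 80.2% of those tested. The sorted values of arrays from different groups differed by at least 0.447 (mean absolute log2) and by at most 0.0811 within a group, as would be expected if the groups had been normalized in separate runs, which could set the shift. A broader range of cells in the S100a10 purifications stays open. A set of 105 housekeeping genes, among them the glycolytic and proteasome lists, kept a median difference of 0.19, between 0 and the median of all genes at 0.56. This value cannot decide it, since the arrays differed less at high intensities. Medians were 20.4 to 21.3 in Glt25d2 and 35.5 to 35.8 in S100a10 arrays, and 99th percentiles 12890 to 13342 and 14765 to 15118. A small difference of abundant genes can therefore come from the scaling. The scaling, the range of cells and any difference in sample preparation cannot be told apart here, because each group lies in its own apparent run.

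The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 10339 probe sets, 5379 of them at least 2-fold, and 5827 genes, each as large in 1 of the 10 splits, where the highest of the others gave 0. For gene lists, 10 of the 10 splits gave at least the 5 lists of the real one, up to 18. The number of lists called at the preset correlation therefore does not set the real grouping apart. These counts point to a structure among the samples, and its cause was not tested.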

How the results depend on the processing

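Results under alternatives chosen before the data were examined are given here, and those under quantile normalization with Glt25d2 replicate 3 left out were added afterwards; the cause of a change was not tested unless stated. Both driver genes kept their direction and passed under every alternative that tested them; with both means at 50 or more Colgalt2, and the ependymal list, gave no value. Counts are probe sets higher in S100a10 and in Glt25d2 cells, the same at 2-fold or more, then genes, against 9405, 934, 5150, 229, 5285 and 542. Without a filter, where more probe sets are tested, 19640 and 5131 probe sets passed, 557 at least 2-fold higher in Glt25d2, and 8351 and 1645 genes. With both means at 50 or more, which removes genes low in 1 group, 2850 and 133 passed at 2-fold. Quantile normalization gave 3289, 4585, 1973, 1789, 2081 and 2390. Median centring gave 3456, 5131, 2213, 1783, 2004 and 3043. Quantile normalization without Glt25d2 replicate 3 gave 4437, 5530, 2108, 1700, 2727 and 2920. Array weights gave 1537 probe sets and 892 genes higher in Glt25d2. Of the 5285 genes, 2004 were also called the same way after centring and 1684 under each of 4 fits: quantile normalization, centring, leaving out Glt25d2 replicate 3, and quantile normalization with that array left out. Of the 542, 492 were without Glt25d2 replicate 3; the rescaled fits move most genes toward Glt25d2 and so do not test them.

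Camera called 2 lists higher in S100a10 and 3 in Glt25d2 cells. Each of the 10 splits of the arrays gave at least as many lists in all, so these counts do not set the real grouping apart. Higher in S100a10 were 1 list without a filter, 1 list with both means at 50 or more, 0 with an estimated correlation and 12 by fry. Higher in Glt25d2 were 1 list after quantile normalization, 10 with array weights, 5 after quantile normalization without Glt25d2 replicate 3, 0 with an estimated correlation and 1 by fry, which compares no list with other genes. Lists that passed in neither fit are counted as kept whatever their sign, so no direction is claimed for them.

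Leaving out 1 array at a time gave 7361 to 11722 probe sets higher in S100a10 and 617 to 1278 in Glt25d2, 4507 to 5613 and 202 to 342 at 2-fold or more, 4263 to 6606 and 369 to 748 genes, and 2 to 2 and 2 to 11 lists. The log2 difference of S100a10 was 2.14 to 2.37 and that of Colgalt2 -6.69 to -6.33. Glt25d2 replicate 3 gave the highest counts when left out, and without Glt25d2 replicate 2 the genes were 4263 and 369, the lowest.

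Both groups number their replicates 1 to 3, with a letter b after the number in the S100a10 titles. Deviations of equally numbered arrays from their group means correlated across probe sets at -0.45, 0.22 and -0.24, and Glt25d2 replicate 3 correlated best with S100a10 replicate 1. Whether the numbers pair the samples stays open. The deviations within a group depend on each other, and in Glt25d2 those of replicate 3 were the largest, so these correlations cannot exclude a pairing. With the replicate number as a block, 558 probe sets and 327 genes were higher in Glt25d2 cells.

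The rule took 118 genes besides the drivers: the 12 of each direction, up to 4 per list and the serotonin receptors. Of these 118, 12 changed sign in some alternative. Of all 161 list members past the threshold, 33 did in at least 1 of the 4 fits above, and 2, Kcnab3 and Ndufb5, were called the other way. Among them were Hltf and Rbfox3, Hltf to -0.21 after quantile normalization and Rbfox3 to -0.18 after centring. After quantile normalization Eng was -0.048, Clic6 -0.38, Jun -0.037, Rps25 -0.041, Htr1a -0.55 and Htr1f -0.28. After centring Clic6 was -0.15, Egr1 -0.25, Jun -0.31, Htr1a -0.42 and Htr1f -0.089. The ribosomal protein list kept its median of -0.21 relative to all genes there, and only its camera direction turned. After quantile normalization without Glt25d2 replicate 3, Clic6 was -0.27, Htr1b -0.084, Kcnk3 -0.073, Map1a -0.079, Jun -0.036, Htr1a -0.41, Htr1f -0.60, Htr2c -0.38 and Htr5a -0.17. Over all alternatives, 1914 values of named genes kept direction and side of the threshold, 138 no longer passed and 4 newly passed. The limit of 50 leaves low genes with a bound only, as for Colgalt2 in S100a10 cells.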

Other observations

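The tests in this part were chosen after the results were seen. Genes of proteins that do not enter the endoplasmic reticulum through a signal sequence at their start, tail-anchored membrane proteins, stood at a median difference of 0.46 with all arrays and 0.56 without Glt25d2 replicate 3. The 70 genes of the chaperone, lysosomal and adhesion lists, chosen after the data were seen, stood at 1.16 with all arrays and 0.23 without that array. Among the arrays of the other line, S100a10 replicate 1 had a median deviation of -0.35 for these 70 genes, against 0.19 and 0.13 in its 2 companions. Immediate early genes deviated by 1.26 in S100a10 replicate 1 and by -0.52 and -0.70 in the other 2 S100a10 arrays.

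The Xist probe sets lay between 6.6 and 15.9 in the 6 arrays, below the limit of 50. The sex of the animals is not inferred from these values of ribosome-bound RNA. Of the sex-linked list, Eif2s3y and Kdm5d were measured and differed by 0.19 (-0.51 after quantile normalization) and 1.07 without passing (limma adjusted p = 0.758 and 0.099).

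The gene next to Colgalt2 on 1 side, and the nearest measured gene on 1 side of S100a10, were each higher in that driver's line. Tsen15, next to Colgalt2 in the RefSeq order for GRCm38.p6, had a mean of 10358 ± 744 in Glt25d2 arrays against 1309 ± 175 (SD, n = 3 each), a log2 difference of -2.99 and rank 10 of 11821 toward that line, while Rgl1 on the other side differed by 0.37, or by -0.46 after quantile normalization. Tchh, 3 genes away and the nearest measured gene on 1 side of S100a10, differed by 3.48 (rank 333), and Them4 on the other side by -0.22. So 2 of the 4 nearest measured genes lay among the 5% of genes most shifted toward the driver's line, a limit set after these values were seen. Copies of a neighbour carried by the BAC and a difference between the cell populations themselves cannot be told apart, since no array of cells without the transgenes is analysed here.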
